A study of Mus musculus with 80 samples.

How the data were processed

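Kidney RNA of 80 mice was measured, 1 array per animal. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns and biotin-labelled cRNA was hybridised to Illumina BeadChips. Genotype, sex, age, chip and organ weights were taken from the labels of each animal, which are separate animals, so that replicates are biological. The submitters' processing notes name lumi, with no version. The steps run with it are not given in the sources used here.

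The deposited table of normalized values holds intensity on a linear scale, with the background subtracted, as the values below 0 show (24.7% and 24.8% of values in the respective sets of chips). Its sorted values are alike within chips A to D and within chips E to J and differ between them (medians of 13.9 and 10.0), so it had been quantile-normalized by set. Non-normalized intensity and a detection p-value per probe were deposited by the authors for both sets. A consolidated table deposited by the authors holds values on a log2-like scale. Columns were matched to animals by name only: 32 arrays of chips A to D could be matched, and 336 columns of per-sample values, belonging to 48 arrays, matched no label and were not used. Each of the 32 matched signal columns correlated best with its own animal in the normalized table, and 23 of 32 columns of the consolidated table did.

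Because of those columns the planned joint background correction and normalization of all 80 arrays could not be run, and the fallback fixed beforehand was used, the deposited normalized values as log2(value + 50). The offset keeps values below 0 and understates the change of dim genes. For the same reason the planned filter of detection on at least 14 of 80 arrays was replaced by a detection p-value below 0.05 on at least 7 of the 32 arrays of chips A to D, and detection on chips E to J stayed unknown. Of 25697 probes, 25594 had an annotation and 23692 a current symbol, and 13977 passed the filter. The probe with the highest mean stood for each of 10453 genes. Of 947 called genes with more than 1 passing probe, 8 had another probe called the opposite way (Actb, Calca, Cnp, Gcnt2, Il1rap, Mtmr3, Rabgap1 and Traf6). Pearson correlations between arrays lay between 0.872 and 0.994, with a median of 0.988 within a group and chip, and 0 pairs of arrays were identical.

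Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend and robust), with terms for the sex-by-genotype group, age and chip. Kidney weight slopes were fitted in 47 mutants on log2 of the kidney to body weight ratio with sex, age and chip, and age slopes per 30 days in 33 controls or as a genotype by age term over 80 arrays. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Before the data were examined, 28 gene lists, these models, the alternatives called planned in the closing section and the rule for named genes were fixed. That rule took the largest absolute log2 changes among called genes with the same sign in both sets (10 up and 10 down for the genotype effect and the kidney weight slope, 5 and 5 for the interaction, sex in controls and age), without clone or predicted names. It added up to 4 members of each list with the smallest adjusted p in the genotype effect, and Pkd1, Hnf4a, Ppara and Ppargc1a. A few genes that the rule names are not reported here. Other genes of the Serpina family were chosen after their values were seen.

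Of the lists, 26 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, 1 had fewer than 3 measured members and 1 checked the sex labels. They hold 702 symbols, of which 535 were measured. Adjusted p-values of lists are over the lists of a comparison. In the genotype effect 3 lists held with an estimated correlation (thick ascending limb, cell cycle, red cell). A list score is the mean log2 over members per animal in the same linear model. Weights were compared with permutation tests, exact where a group held fewer than 10 animals and otherwise with 100000 resamples (SciPy 1.17.1 in Python 3.11.15), two-sided. Where all arrays of a group lacked detection on chips A to D, a bound is given against the lowest detected signal. Correlations and overlaps between comparisons that share arrays are set beside simulated values with no effect and beside n1 × n2 / N for independent lists.

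On simulated data with 200 of 10453 genes changed, 92.5% of genes changed by 1.2-fold were recovered for the genotype effect and 35.8% for the interaction. At 1.5-fold it was 100.0% and 94.0%. Alternatives covered background, normalization, offset, filter, probes per gene, chip and age terms, array weights, sets of chips, left-out chips and animals, and thresholds. Figures were drawn with matplotlib 3.10.9.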

Results

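Gene expression was measured in whole kidneys of 80 mice on Illumina BeadChip arrays, with 1 array per animal. All animals carried conditional Pkd1 alleles and received tamoxifen at 0.2 mg per g of body weight on day 40 after birth. Controls lacked the tamoxifen-inducible cre recombinase and mutants carried it, so that Pkd1, the gene most often mutated in autosomal dominant polycystic kidney disease, was to be deleted in adult mutants only. Presence of the recombinase and loss of Pkd1 therefore cannot be told apart in these groups. Kidneys were taken between day 102 and day 210. There were 14 control females, 19 control males, 21 mutant females and 26 mutant males. The arrays lay on 10 chips of 8 arrays each, with controls and mutants on every chip. Chips A to D (32 arrays) and chips E to J (48 arrays) had been normalized as separate sets, and values were compared within chips. Between 44.5% and 54.3% of probes were detected on each of the 32 arrays that had a detection p-value. The number of arrays limits the precision of every value below. Fold changes are on the scale of log2(signal + 50), which understates the change of dim genes.

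Mutant kidneys were heavier for the size of the animal. The ratio used throughout is the mean weight of both kidneys, not their sum, over body weight. The kidney to body weight ratio was 0.0113 ± 0.00666 (SD, n = 21) in mutant females and 0.00657 ± 0.000743 (SD, n = 14) in control females, a 1.54-fold difference of mean log2 ratios (two-sided permutation p = 1.60e-04, adjusted p = 2.40e-04 over 6 weight comparisons). In males the ratio was 0.0161 ± 0.0143 (SD, n = 26) in mutants and 0.00639 ± 0.000696 (SD, n = 19) in controls, a 2.08-fold difference (permutation p = 2.00e-05, the smallest that the 100000 resamples can give, adjusted p = 1.20e-04). The ratio lay above the highest control of the same sex in 15 of 21 mutant females and 19 of 26 mutant males. Within the sets of chips the difference was 1.92-fold on chips A to D and 1.28-fold on chips E to J in females (exact permutation p = 1.03e-04 and 0.0258) and 3.37-fold and 1.76-fold in males (exact permutation p = 3.11e-04 and permutation p = 2.00e-05).

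**Figure D1:**
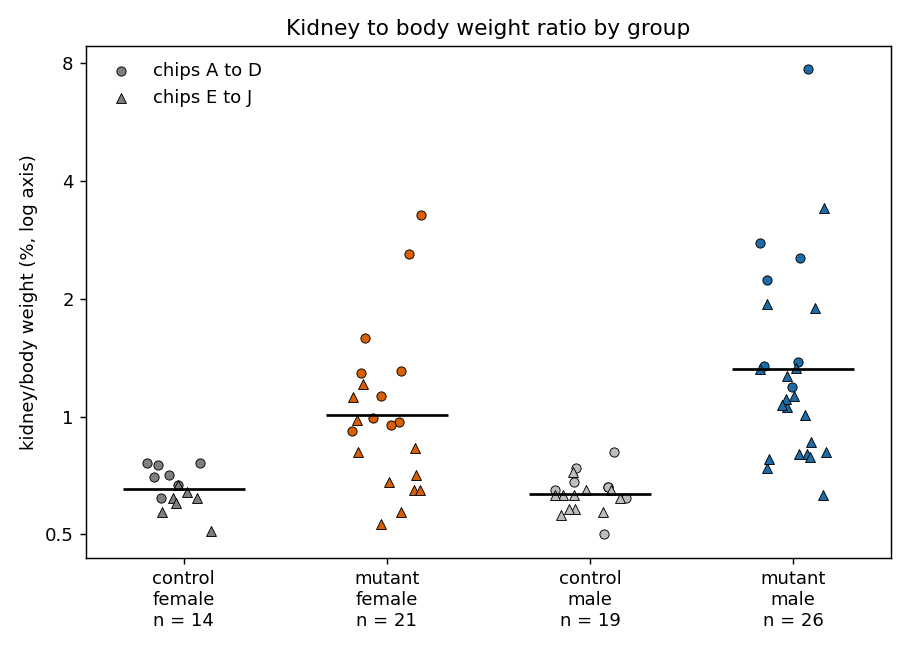
Kidney to body weight ratio (mean weight of both kidneys over body weight) in percent on a log axis, with 1 point per animal in 4 groups. Circles are chips A to D and triangles chips E to J, and lines mark the mean of log2 values. Control ratios lie close together in both sexes, and 15 of 21 mutant females and 19 of 26 mutant males lie above the highest control of their sex.

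Liver weights were labelled only for animals of chips E to J. The liver to body weight ratio was 0.0721 ± 0.0198 (SD, n = 11) in mutant females and 0.0421 ± 0.00418 (SD, n = 7) in control females, a 1.67-fold difference (exact permutation p = 6.28e-05, adjusted p = 1.26e-04), with 11 of 11 mutants above the highest control. In males it was 0.0553 ± 0.0151 (SD, n = 18) against 0.0384 ± 0.00461 (SD, n = 11), a 1.41-fold difference (permutation p = 4.00e-05, adjusted p = 1.20e-04), with 13 of 18 mutants above the highest control. Mutant males weighed 28.4 g ± 2.53 (SD, n = 26) and control males 32.4 g ± 4.40 (SD, n = 19; permutation p = 4.20e-04, adjusted p = 5.04e-04). The male body weight difference was -3.61 g on chips A to D (exact permutation p = 0.114) and -3.37 g on chips E to J (permutation p = 0.0025). Mutant males were younger, at 144.6 days ± 35.3 (SD, n = 26) against 157.6 ± 32.3 (SD, n = 19) in control males. Mean ages were 160.9 days in mutant females and 159.6 in control females. None of the weight tests held an age term, so age and genotype are not separated in the male difference. Body weights of females differed by -0.44 g (permutation p = 0.503). Among 47 mutants the kidney to body weight ratio on the log2 scale went up with age (Pearson r = 0.632, Spearman rho = 0.632, each with a permutation p of 1.00e-05, the smallest possible). Without the 2 animals farthest from the median age r was 0.583. Within sets it was 0.548 on chips A to D (permutation p = 0.0219, rho = 0.700, p = 0.0026) and 0.357 on chips E to J (permutation p = 0.0525, rho = 0.375, p = 0.0427). In the 33 controls r was 0.224 (permutation p = 0.209) and rho 0.258 (permutation p = 0.146), with r of -0.179 on chips A to D (permutation p = 0.547) and -0.038 on chips E to J (permutation p = 0.884).

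Pkd1 itself was read by 1 probe that starts at position 13532 of its transcript, outside the part that is deleted, so it checks nothing about the deletion. It was detected on 24 of 32 arrays of chips A to D and differed by -0.08 (SE 0.03) log2 between mutants and controls (limma adjusted p = 0.0386). This call was lost within each set (adjusted p = 0.227 on chips A to D and 0.256 on chips E to J), without a chip term (0.119), without a detection filter (0.0627), without the mutant with the heaviest kidneys (0.0546) and without chip B, C, D, E, G or I. Signals of Xist (1 of its 2 probes) and Eif2s3y separated all animals labelled female from all labelled male. Ranges of the other Xist probe and of all probes of Ddx3y, Kdm5d and Uty overlapped between the sexes. For 1 Ddx3y probe the highest female lay at log2 7.94 and the lowest male at 7.32.

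In mutant kidneys cell cycle genes rose as a list and markers of the thick ascending limb and of red cells fell, each with an adjusted p of 0.0297 with an estimated correlation. Most injury and macrophage genes also rose and many mitochondrial genes fell, but as lists they lost their calls with an estimated correlation (adjusted p = 0.146 for injury and for macrophage markers, 0.177 for the citric acid cycle, 0.197 for the respiratory chain and 0.389 for fatty acid oxidation). Their list scores, which were added after the data were seen, were called in the linear model. Scores were 0.76 for macrophage markers (adjusted p = 1.34e-07) and 0.55 for injury genes (adjusted p = 1.61e-07). For the citric acid cycle, respiratory chain and fatty acid oxidation they were -0.17, -0.10 and -0.15 (adjusted p = 9.45e-06, 1.44e-05 and 0.0032). Lcn2 and Havcr1, secreted and surface markers of tubular injury, rose 5.00-fold (log2 2.32, SE 0.32, adjusted p = 2.09e-08) and 3.62-fold (log2 1.85, SE 0.28, adjusted p = 2.10e-07) in 47 mutants against 33 controls. Lyz2, a macrophage lysozyme, rose by 1.85 (SE 0.23), and Timp1, an inhibitor of matrix proteases, by 1.21 (SE 0.21). Hba-a1, an alpha globin, fell 2.84-fold (log2 -1.51, SE 0.15, adjusted p = 1.52e-12). The smallest adjusted p among named genes belonged to Lad1, an anchoring filament protein, which fell 2.30-fold (log2 -1.20, SE 0.06, adjusted p = 7.05e-26). Other genes with the largest rises were Serpina10 (log2 1.81), Lyz1 (1.72), H2ac7 (1.22), Serpina3g (1.20) and Ptgds, a prostaglandin D synthase (1.18, SE 0.09). Dao, a D-amino acid oxidase, rose by 1.31 with an SE of 0.52 (adjusted p = 0.0396) and had that sign on 8 of 10 chips. Other genes with the largest falls were Cyp2d12 (log2 -1.36), Hbb-b2 (-1.25), Alas2, the red cell enzyme of heme synthesis (-1.23), Car15 (-1.15), Egf (-1.10), Guca2b (-1.10), Cwh43 (-1.08) and Ppp1r1b (-1.06). All named genes of this paragraph but Dao had the same sign on 10 of 10 chips. The rule had picked them for the same sign in both sets of chips, and chip H held 1 control and chip G 2. Lyz1 and Lyz2 are near-identical copies, and Hba-a1, Hbb-b2 and Cyp2d12 each belong to a family of similar genes. Probes may not tell such relatives apart.

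Of 10453 genes tested, 3755 passed the threshold (limma, adjusted p below 0.05), 1959 higher and 1796 lower in mutants. Changes were small for most of them: 148 rose and 53 fell by over 1.5-fold. Chips A to D alone gave 3993 genes and chips E to J alone 1022, and 97.6% of the called genes had the same sign in both sets. Since genes were called on both sets together, part of that agreement is built in. In the main result 52.2% of the called genes were higher in mutants. On chips A to D with neqc background correction this share was 51.2% after quantile normalization and 79.4% after scaling to a common median, and the median of all genes in males was -0.01 and 0.12.

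The study's title concerns fatty acid oxidation. Of 23 measured genes of mitochondrial fatty acid oxidation 11 fell, also when adjusted over the list alone, and 0 rose (limma, 11 at the adjusted threshold, median log2 -0.16). They included the acetyl-CoA synthetase Acss1 (log2 -0.34, SE 0.07), the short-chain dehydrogenase Acads (-0.33, SE 0.07), Etfdh, which passes electrons to the respiratory chain (-0.24), and Hadhsc (-0.22). The list was lower than other genes by camera with a preset correlation (adjusted p = 6.33e-04), and the adjusted p was 0.389 with an estimated correlation. On chips A to D the list score, the mean log2 over members, was -0.30 (SE 0.088) lower in mutants and on chips E to J it differed by -0.02 (SE 0.043), where the camera call was lost (adjusted p = 0.604). Among peroxisomal oxidation genes and PPAR alpha targets 9 of 26 fell and 1 rose (adjusted p = 0.0044, and 0.389 with an estimated correlation). Pecr (-0.55), Acox3 (-0.46) and Acot8 (-0.42) fell, and Cyp4a12b, a fatty acid hydroxylase, rose (0.48). This call too was lost on chips E to J (median -0.01, adjusted p = 0.306). Ppara, the receptor that controls many of these genes, differed by -0.06 (SE 0.04, adjusted p = 0.172).

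In the citric acid cycle 16 of 21 genes fell (17 when adjusted over the list alone) and 0 rose, among them Pdhb (-0.32), Pdha1 (-0.29), Sdhc (-0.28) and Fh1 (-0.19). The camera adjusted p was 2.92e-06, and the adjusted p was 0.177 with an estimated correlation. Of 51 genes of the respiratory chain and ATP synthase 26 fell (30 when adjusted over the list alone), at a median of -0.10, with Ndufb7 at -0.21, Ndufs8 at -0.19 and Atp5o at -0.16 (adjusted p = 8.81e-07, and 0.197 with an estimated correlation). For gluconeogenesis, 6 of 7 genes fell and 1 rose (adjusted p = 0.0397, and 0.311 with an estimated correlation). Pck1, its rate-limiting enzyme, fell (-0.57), as did Fbp1 (-0.24) and Ppargc1a, a coactivator of mitochondrial genes (-0.24), whereas Fbp2 rose (0.40). On chips E to J the gluconeogenesis call was lost (median -0.07, adjusted p = 0.463). Glycolysis as a list was not called (3 of 15 rose, 3 fell, adjusted p = 0.794): Pfkp (0.18) and Tpi1 (0.11) rose, Pfkm (-0.31) and Aldoa (-0.14) fell. Cholesterol synthesis (2 of 19 rose, 3 fell, adjusted p = 0.420) held falls of Ebp (-0.28), Cyp51 (-0.28) and Tm7sf2 (-0.20). Fatty acid synthesis (2 of 14 rose, 2 fell, adjusted p = 0.744) held rises of Fads1 (0.31) and Elovl5 (0.20) and falls of the desaturase Scd1 (-0.66) and Me1 (-0.29).

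Of 18 measured markers of the thick ascending limb and distal tubule 14 fell and 0 rose (median -0.34, adjusted p = 3.71e-10, and 0.0297 with an estimated correlation), with Ppp1r1a at -0.72, Tmem52b at -0.54 and the potassium channel Kcnj1 at -0.38. Among proximal tubule markers 17 of 32 fell (20 when adjusted over the list alone), including Dpep1 (-0.77), the dicarboxylate transporter Slc13a3 (-0.69), the glucose transporter Slc5a2 (-0.65) and Slc7a7 (-0.34). Their camera adjusted p was 8.18e-06, the adjusted p was 0.311 with an estimated correlation, and the call was lost on chips E to J (median -0.04, adjusted p = 0.190). Hnf4a, a regulator of proximal tubule genes, fell by 0.15 (SE 0.05, adjusted p = 0.0212). Collecting duct markers fell in 9 of 19 cases (10 when adjusted over the list alone) and rose in 1 (adjusted p = 0.0012, and 0.146 with an estimated correlation), among them the anion exchangers Slc4a1 (-0.77), which red cells also express, and Slc4a9 (-0.43), and the ammonia transporters Rhbg (-0.35) and Rhcg (-0.30). Podocyte markers were not called as a list by camera (1 of 9 rose, 3 fell, adjusted p = 0.357), whereas their list score was (-0.05, SE 0.023, linear model, adjusted p = 0.0326). Cdkn1c (-0.23) and Clic3 (-0.16) fell and Col4a4 (0.22) rose. All 4 measured red cell genes fell (median -1.24, adjusted p = 4.88e-06, and 0.0297 with an estimated correlation), and their score was lower on 10 of 10 chips.

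All 26 macrophage and dendritic cell markers rose, at a median of 0.76, with Mrc1 at 0.97 and the growth factor receptor Csf1r at 0.37 (adjusted p = 1.21e-16, and 0.146 with an estimated correlation). Complement genes rose in 11 of 16 cases and fell in 1, with C1qb at 1.10, C1qc at 1.08, C4b at 0.87 and C2 at 0.61 (adjusted p = 1.86e-06, and 0.133 with an estimated correlation). C1qb and C1qc are also on the macrophage list. T cell genes Cd3g (0.39), Cd3d (0.33) and Cd8b1 (0.31) and the B cell gene Cd79b (0.22) were among 9 of 12 lymphocyte markers that rose (adjusted p = 6.33e-04, and 0.177 with an estimated correlation). Interferon response genes rose in 20 of 29 cases (22 when adjusted over the list alone) and fell in 2, with Gbp2 at 0.94, Ifit3 at 0.64, Ifit2 at 0.48 and Oasl2 at 0.35 (adjusted p = 9.73e-07, and 0.206 with an estimated correlation). Of 33 fibroblast and extracellular matrix genes 26 rose and 0 fell (median 0.41, adjusted p = 4.73e-12, and 0.197 with an estimated correlation), including Sparc (0.87), Dcn (0.77) and Fstl1 (0.75). Of 35 tubular injury genes 29 rose and 0 fell (median 0.53, adjusted p = 3.29e-14, and 0.146 with an estimated correlation), including Gdf15 (0.75), S100a11 (0.71) and Cryab (0.58). Endothelial markers rose in 9 of 18 cases and fell in 1, with Robo4 at 0.32, Plvap at 0.32, Egfl7 at 0.25 and Eng at 0.22 (adjusted p = 0.0137, and 0.265 with an estimated correlation), and the call was lost on chips E to J (median 0.04, adjusted p = 0.268).

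Cell cycle genes rose in 27 of 30 cases (28 when adjusted over the list alone) and fell in 2, at a median of 0.37 (adjusted p = 4.70e-18, and 0.0297 with an estimated correlation). Prc1, which organizes the spindle midzone, rose by 1.03, Uhrf1 by 0.91, Cdc20 by 0.63 and the kinase Cdk1 by 0.58. Among cilium and cystic disease genes Pkd2, whose product forms a complex with that of Pkd1, rose 1.82-fold (log2 0.87, SE 0.05, adjusted p = 1.04e-24). The transcription factor gene Glis2 rose by 0.53 (SE 0.05), Bicc1 by 0.24 and Pkhd1 by 0.20. This list as a whole was not called by camera (5 of 27 rose, 3 fell, adjusted p = 0.505), and its median was -0.01 where its mean was 0.05. Its list score, in the linear model, was called (0.05, SE 0.011, adjusted p = 2.16e-04). Glutathione genes likewise went both ways (3 of 24 rose, 7 fell, 8 when adjusted over the list alone, adjusted p = 0.102), with falls of Gsta2 (-0.87), Gsta4 (-0.39) and Gstp1 (-0.35) and a rise of Ephx1 (0.46). Genes known to be higher in male kidneys were not called (1 of 12 rose, 4 fell, adjusted p = 0.237): Cyp7b1 (-0.55), Ddc (-0.39) and Slco1a1 (-0.08) fell and Hsd11b1 (0.26) rose. Those known to be higher in female kidneys were not called by camera either (1 of 10 rose, 3 fell, 4 when adjusted over the list alone, adjusted p = 0.320, median 0.02 and mean -0.16). Their list score, in the linear model, was called (-0.16, SE 0.055, adjusted p = 0.0079). Slc22a7 (-0.49) and Kynu (-0.24) fell and Abcc3 (0.30) rose. Of 7 fat cell markers Lep fell by 0.15 and the other 6 did not pass (adjusted p = 0.149). Of the adrenal cortex markers, measured because the gland lies on the kidney, Akr1b7 fell by 0.15 (adjusted p = 0.0264) and Cyp11b2 differed by -0.07 (adjusted p = 0.104), and with fewer than 3 members measured this list was not tested.

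**Figure D2:**
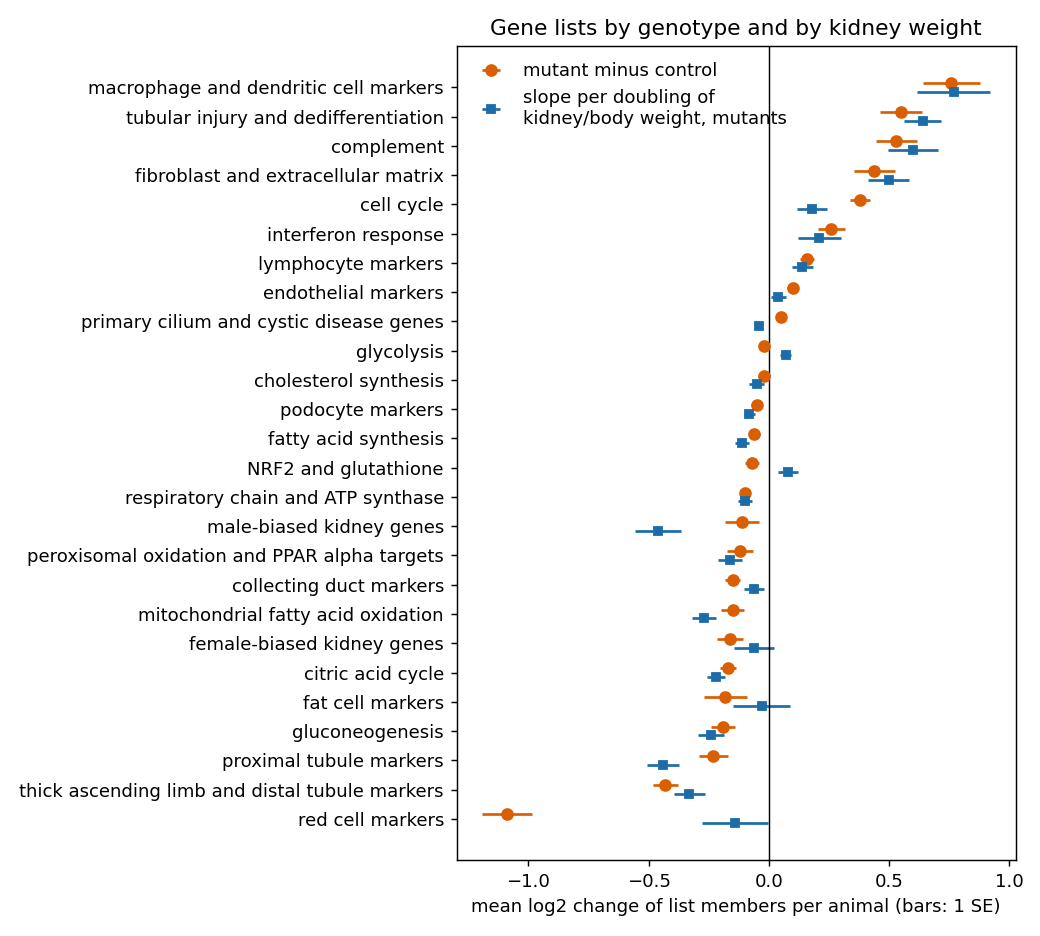
Mean log2 change of the members of 26 gene lists per animal, as mutant minus control (circles) and as the slope per doubling of kidney to body weight ratio within mutants (squares), with bars of 1 SE. Macrophage markers lie highest by genotype (0.76) and red cell markers lowest (-1.09), and red cell markers have a slope of -0.14 (SE 0.136).

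The effect was then taken in each sex. In females 966 genes passed (517 higher, 449 lower), and in males 3332 (1779 higher, 1553 lower). The count in females was 334 without chip C, 565 without chip D, 544 without a chip term and 131 on chips E to J, and in males it was 2136 without a chip term and 1103 on chips E to J. With median scaling of chips A to D, 488 genes were higher and 116 lower in females, and 2461 higher and 554 lower in males. Lcn2 rose by 1.89 in females and 2.76 in males, Havcr1 by 1.48 and 2.23, and Hba-a1 fell by 1.06 and 1.95. Pkd2 rose by 0.83 in females and 0.90 in males. Over the 3538 genes called in either sex 91.0% had the same sign and the correlation across genes was 0.850. Genes are not independent replicates. The lists shared 414 higher genes, against 88.0 for independent lists, and 341 lower genes against 66.7. Over all genes the correlation was 0.787 and the covariance 0.0302, and simulated noise on the same arrays gave -0.018 and -0.0001.

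A test of the difference itself found 26 genes, of which 10 had a higher effect in males and 16 a lower one. Serpina6, which encodes the corticosteroid-binding globulin, was higher by 1.66 (SE 0.11, adjusted p = 9.03e-19) in mutant females and differed by 0.13 (SE 0.11, adjusted p = 0.349) in males (adjusted p of the difference 1.19e-10). It was not detected on any control array of chips A to D and on 1 of 7 arrays of mutant males, so the fitted values are no bounds, and on those chips its signal in mutant females was at least 2.08-fold that of control females. Serpina1d and Serpina1b, which encode alpha-1-antitrypsins, were higher by 1.42 and 1.37 in mutant females. In males Serpina1d fell by 0.33 (adjusted p = 0.0313) and Serpina1b differed by 0.35 (adjusted p = 0.0665). Gsta2, a glutathione transferase, fell by 0.43 in females and 1.30 in males. C2 rose by 0.36 in females and 0.86 in males, Pcdh7 by 0.23 and 0.64, and Pcolce2, which promotes procollagen processing, fell by 0.80 and 0.22. Smoc1 rose by 0.52 in males, where on chips A to D it was detected on 1 of 8 control and 5 of 7 mutant arrays. In females it was detected on 0 of 7 control and 1 of 10 mutant arrays, so that no fold is given and its difference between the sexes rests on signals near background. Selenop, which carries selenium, fell by 0.46 in females and differed by 0.15 in males, and Cyp2d9 rose by 0.54 in females and fell by 0.49 in males. Camera called several lists here, such as the cell cycle (adjusted p = 7.60e-08), but 0 calls of camera held with an estimated correlation, where the lowest adjusted p was 0.296. Chips A to D alone gave 4 genes and chips E to J alone 11.

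**Figure D3:**
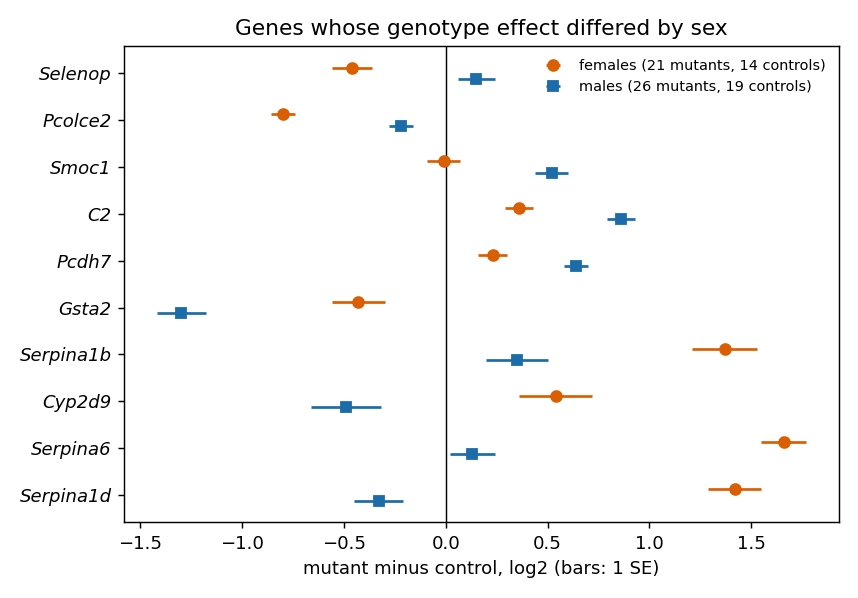
Genotype effect in females (circles) and males (squares) on the log2 scale, with bars of 1 SE, for the 10 named genes called by the test of the difference. Serpina6 lies at 1.66 in females and 0.13 in males, and Serpina1d at 1.42 and -0.33, while Smoc1 in females lies near background.

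Control males and females differed in many genes. Acsm3 (log2 5.58, SE 0.30, adjusted p = 2.07e-25), Cyp2j13 (4.74), Cyp4a12a (4.30), the steroid hydroxylase Cyp7b1 (4.08) and Cyp2d9 (2.94) were higher in males. Ugt1a2 (-5.33, SE 0.16, adjusted p = 3.50e-40), the growth factor gene Igf2 (-3.67), the histidine decarboxylase gene Hdc (-3.28), the transporter Abcc3 (-3.06) and Cyp4a14 (-3.01) were higher in females. Abcc3 was not detected in any control male on chips A to D, where females were at least 7.69-fold higher. Of 12 genes fixed as higher in male kidneys 10 were higher in males and 2 lower (median 1.67, adjusted p = 1.82e-17, and 4.84e-04 with an estimated correlation). Of 10 fixed as higher in female kidneys 6 were higher in females and 3 in males (median -1.32, adjusted p = 7.18e-04, and 0.0396 with an estimated correlation). Markers of the collecting duct (12 of 19 lower in males, median -0.36, adjusted p = 5.41e-05, and 0.0396 with an estimated correlation), of podocytes (5 of 9 lower, median -0.34, adjusted p = 0.0026, and 0.0396) and of the thick ascending limb (12 of 18 lower, median -0.39, adjusted p = 5.41e-05, and 0.128 with an estimated correlation) were lower in males. In all, 2872 genes passed in controls (1292 higher in males, 1580 lower) and 3019 in mutants (1393 higher, 1626 lower). With median scaling of chips A to D, 654 genes were higher and 448 lower in males among controls, and 761 and 381 among mutants. In mutants, markers of the thick ascending limb (16 of 18), of the collecting duct (16 of 19) and of podocytes (7 of 9) were lower in males, each with an adjusted p of 0.0062 with an estimated correlation. Both comparisons shared 869 male-higher genes, against 172.2 for independent lists, and 1029 female-higher genes against 245.8. The correlation across all genes was 0.872, and simulated noise gave -0.006.

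Among mutants, tubular injury genes rose with kidney weight as a list (adjusted p = 0.0394 with an estimated correlation). Most macrophage and complement genes also rose and most proximal tubule markers fell, but as lists they lost their calls with an estimated correlation (adjusted p = 0.130, 0.129 and 0.111). Slopes of their added list scores were 0.77, 0.60 and -0.44 and were called in the linear model (adjusted p = 4.24e-05, 7.56e-06 and 1.39e-06). For each doubling of the kidney to body weight ratio in 47 mutants Lcn2 rose by 2.16 (SE 0.35, adjusted p = 1.55e-05), Lyz2 by 1.59, Serpina10 by 1.49, Timp1 by 1.44, Lyz1 by 1.43, the acute phase gene Hp by 1.41, Ms4a6d by 1.41, Havcr1 by 1.28, the chemokine gene Ccl9 by 1.26 and C3 by 1.25. Egf, made in the distal tubule, fell by 1.39 (SE 0.24, adjusted p = 3.49e-05), the methyltransferase gene Inmt by 1.43, the calcium-binding Pvalb by 1.27, Dnase1 by 1.21 and Acsm3 by 1.18. Mfsd2a (-0.96), Aspdh (-0.95), Slc22a22 (-0.89), Nccrp1 (-0.88) and Wfdc15b (-0.85) also fell. Several genes that differed strongly by genotype did not move with kidney weight past the threshold. The slope was -0.01 (SE 0.07, adjusted p = 0.948) for Pkd2, -0.22 (SE 0.25, adjusted p = 0.565) for Hba-a1, 0.14 (SE 0.12, adjusted p = 0.417) for Ptgds and -0.22 (SE 0.10, adjusted p = 0.116) for Car15.

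Tubular injury genes rose with kidney weight in 30 of 35 cases (median 0.64 per doubling, adjusted p = 9.06e-22, and 0.0394 with an estimated correlation), and no other list held with an estimated correlation. Matrix genes rose in 28 of 33 cases (median 0.43, adjusted p = 4.59e-16, and 0.129), macrophage markers in 23 of 26 (0.73, adjusted p = 4.31e-15, and 0.130) and complement genes in 11 of 16 (0.64, adjusted p = 2.11e-05, and 0.129), where the latter p-values are those with an estimated correlation. Proximal tubule markers fell in 27 of 32 cases (29 when adjusted over the list alone, median -0.48, adjusted p = 2.31e-15, and 0.111 with an estimated correlation). Genes of fatty acid oxidation fell in 15 of 23 cases (17 when adjusted over the list alone, median -0.24, adjusted p = 5.57e-09, and 0.129 with an estimated correlation). The slope of the fatty acid oxidation score was -0.39 (SE 0.069) in the 17 mutants of chips A to D and -0.16 (SE 0.041) in the 30 of chips E to J. Genes fixed as higher in male kidneys fell in 9 of 12 cases (median -0.47, adjusted p = 1.40e-04, and 0.130 with an estimated correlation). Of the 4 red cell genes 0 moved in limma or as a list (median -0.15, camera adjusted p = 0.679). In all, 3028 genes passed (1569 rising, 1459 falling), against 491 on ranks of the ratio (341 rising, 150 falling), 1839 without the 2 animals farthest from the median ratio and 1890 without chip B. They shared 1064 rising and 779 falling genes with the genotype effect, against 294.0 and 250.7 for independent lists. The covariance of both changes across genes was 0.0293, and 0.0001 in simulated noise on the same arrays. Chips E to J alone gave 1042 genes.

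**Figure D4:**
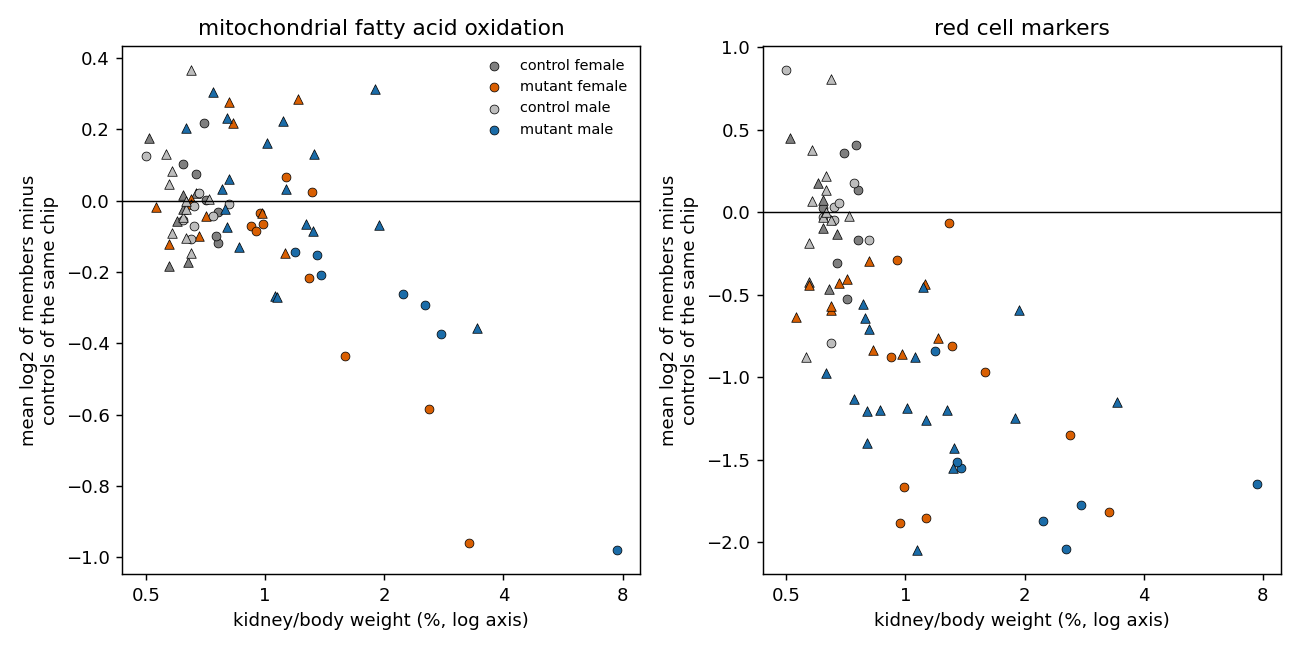
Mean log2 signal of fatty acid oxidation genes (left) and red cell genes (right) per animal, relative to controls of the same chip, against kidney to body weight ratio in percent on a log axis; circles are chips A to D and triangles chips E to J. Fatty acid oxidation scores fall with the ratio within mutants (slopes of -0.39 and -0.16 per doubling in the respective sets), and the slope of the red cell score is -0.14 (SE 0.136).

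Age was tested in controls and as a difference between genotypes. In the 33 controls the mitochondrial carrier gene Slc25a30 rose by 0.33 (SE 0.05, adjusted p = 0.0028) and the lectin gene Lgals4 by 0.30 (SE 0.05, adjusted p = 0.0240) per 30 days, and no other gene passed (2 of 10453, 641 at an unadjusted p below 0.05). Both calls were lost within sets, where limma called 1 other gene on chips A to D and 0 on chips E to J (618 at an unadjusted p below 0.05). They were lost without chip C too, where it called 0 (464). The count depended on the chip term: 4337 genes passed without it (3455 rising, 882 falling) and 29 with chip as a random block. Controls were 148 to 210 days old on chips A to D and 106 to 171 on chips E to J, which were normalized separately. Without a chip term the slope thus mixes age with set of chips, and the 4337 genes are no measure of age alone. Peroxisomal (adjusted p = 8.08e-11, and 0.141 with an estimated correlation) and mitochondrial fatty acid oxidation genes (adjusted p = 1.86e-07, and 0.164) were shifted up by camera, with 0 members called by limma (6 and 5 when adjusted over the list alone). In mutants relative to controls Lcn2 rose by 1.37 (SE 0.24, adjusted p = 4.64e-05) per 30 days, Havcr1 by 1.36, Serpina10 by 1.20, Timp1 by 0.94 and the fibrinogen gene Fgg by 0.87. Pvalb (-0.66), Egf (-0.64), Hbb-b2 (-0.52) and Nccrp1 (-0.49) fell. Matrix genes rose in 30 of 33 cases (median 0.40, adjusted p = 1.03e-29, and 0.067 with an estimated correlation), injury genes in 27 of 35 (0.31, adjusted p = 1.27e-22, and 0.067) and macrophage markers in 25 of 26 (0.44, adjusted p = 1.96e-15, and 0.109). Fatty acid oxidation genes fell in 17 of 23 cases (21 when adjusted over the list alone, median -0.17, adjusted p = 1.21e-10, and 0.109 with an estimated correlation), and proximal tubule markers in 18 of 32 (25 when adjusted over the list alone, median -0.25, adjusted p = 5.79e-11, and 0.109). In all, 2064 genes passed (1153 higher slopes in mutants, 911 lower). Within sets limma called 0 genes on chips E to J (567 at an unadjusted p below 0.05) and 0 on chips A to D (2224), and 85.4% of the called genes had the same sign in both sets. Counts and directions depended on the processing: chips A to D gave 125 higher and 22 lower slopes after neqc, 106 and 12 without background correction, 359 and 12 after median scaling and 11 and 6 in the consolidated table, and all arrays without a chip term gave 636 and 281.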

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

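Tests on red cell transcripts, on the Serpina6 probe and on tubule cell shares were chosen only after the results they bear on were seen, as were the list scores within sets of chips, after joint normalization and after median scaling.

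A test of the difference itself called 10 named genes as differing between the sexes in the effect of genotype, with Smoc1 resting on signals near background. As male minus female effect on the log2 scale, the difference was 0.61 for Selenop, 0.58 for Pcolce2, 0.50 for C2 and 0.41 for Pcdh7. It was -1.75 for Serpina1d, -1.52 for Serpina6, -1.03 for Cyp2d9, -1.03 for Serpina1b and -0.88 for Gsta2 (limma adjusted p between 1.19e-10 and 0.0382). For Smoc1 the fitted value was 0.53, which is no measured difference, since on chips A to D it was detected on 0 of 7 control and 1 of 10 mutant females. Serpina6 was detected on no control there, so that its value rests partly on signals near background. The effect on log2 kidney to body weight ratio was also larger in males, by 0.81 on chips A to D (permutation p = 0.0417) and 0.47 on chips E to J (permutation p = 0.0319), whereas over all animals the difference was 0.43 (permutation p = 0.0635). That pooled comparison held no term for set of chips, and the sexes were spread unevenly over the sets. On chips A to D lay 7 of 26 mutant males and 10 of 21 mutant females.

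Serpina6 and 3 Serpina1 genes were higher in mutant females with a smaller or opposite change in males. Those Serpina1 genes already had higher mean signals in control males than in control females. On chips A to D Serpina1d averaged 689.0 in control females, 1983.8 in control males, 1988.5 in mutant females and 1440.8 in mutant males. In the same order Serpina1b averaged 571.6, 2413.9, 2014.9 and 2885.9, and Serpina1a 85.6, 431.2, 314.2 and 396.6. Serpina6 was near background in controls of both sexes there (-3.6 in females and -11.7 in males). A Serpina6 probe that also binds Serpina1 transcripts is argued against, since no measured Serpina1 gene reached over 0.25 of the log2 difference of Serpina6 both against control females and against mutant males, but the Serpina1 probes may read each other's transcripts. Liver tissue in the samples is argued against as well, since the score of 5 liver markers had a male minus female effect of 0.06 (SE 0.119), although Ttr (mean log2 11.01) and Apoc3 (8.81) are bright in these kidneys on average. A genotype-linked variant near the gene cluster stays open: 1 of 20 neighbouring genes was called in females against 9.2% of all genes, within the spread of so few genes. A sex-dependent response to the loss of Pkd1 or to the recombinase is a further open explanation.

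Fatty acid oxidation genes were lower in mutants, with a score of -0.30 (SE 0.088) on chips A to D and -0.02 (SE 0.043) on chips E to J. The authors' processing of chips A to D is argued against by scores of -0.32 (SE 0.093) with neqc and -0.24 (SE 0.094) with median scaling, but separate normalization of the sets stays open, since normalizing all 80 arrays together (-0.15, SE 0.047) moved 0.05% of genes by over 1 SE and so tests little. A lower share of proximal tubule cells with no other change is argued against too. Markers of the thick ascending limb and of endothelial cells moved apart by -0.52 (SE 0.056). A lower share along with other changes stays open, since that test did not compare fatty acid oxidation with proximal tubule markers. Proximal tubule scores were -0.44 (SE 0.122) on chips A to D and -0.05 (SE 0.041) on chips E to J. Their slopes per doubling of the kidney to body weight ratio were -0.62 (SE 0.091) and -0.27 (SE 0.053), beside -0.39 and -0.16 for fatty acid oxidation. Kidney enlargement stays open. The score differed from controls by 0.05 (SE 0.046) in 14 mutants with ratios up to the highest control (0.0081, a male on chip B). All 14 lay on chips E to J, where the highest control was 0.0067 in females and 0.0072 in males. There 18 of 19 mutant males and 7 of 11 mutant females exceeded the highest control of their sex. Several of the 14 were thus enlarged against their own set, so they cannot decide on enlargement. They were also picked by an outcome and were 124.6 days old on average against 163.4 in other mutants. Enlargement, age and set of chips remain entangled.

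Red cell transcripts were lower in mutants on 10 of 10 chips. Dilution of a fixed amount of blood by kidney RNA that grows in proportion to kidney weight is argued against. This holds among mutants of like age, since the model held an age term. Slopes per doubling of kidney weight were -0.14 (SE 0.136) for the score and -0.22 (SE 0.249) for Hba-a1, where such dilution needs -0.55 and -0.99 on this scale. Whether kidney RNA grew in proportion to weight was not measured, and where it did not, dilution stays open. In mutants relative to controls the red cell score changed by -0.30 per 30 days (SE 0.089, linear model of list scores, adjusted p = 0.0023). These slopes leave out that change with age, and no slope without an age term was compared with dilution. Less blood in mutant kidneys stays open: Hba-a1 and Hbb-b1 fell by amounts that differ by 1.15 (SE 0.185), but only Hba-a1 is bright enough for its fall to be read in full, a condition set after that difference was seen. An effect of the recombinase cannot be told apart from the loss of Pkd1, since there were 0 cre-positive animals that keep Pkd1.

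Counts of called genes were set against 100 splits of the same animals per comparison, the real one included. Only the real split (1 of 100) gave as many genes for the genotype effect (3755, highest other 4), in females (966, 19) and in males (3332, 25). The same held for sex in controls (2872, 2) and in mutants (3019, 45) and for the kidney weight slope (3028, 453). Chance is argued against for these, at a share of 0.01, the lowest that 100 splits can give. Only the real split also gave as many for the interaction (26, 2) and the age difference (2064, 1219). Their splits shuffled genotype within each sex, which removed the genotype effect as well. They are therefore no test of the interaction or the age difference alone, and chance is not excluded there. For age in controls 2 of 100 splits gave as many as the real 2 genes. A split other than the real one called 34, many times the real count, and 96 called 0. The 34 genes point to a structure of the samples, although genes that vary together may also give such a count, and neither was tested. The 453 and 1219 genes above are large as well, although the median of the other splits was 0 in both.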

How the results depend on the processing

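Alternatives named as added were chosen after seeing the data; the others were planned. Under the alternatives that were run list by list, all with the preset correlation, gene lists stayed on their side of the threshold in 673 cases, lost a call in 15, gained one in 7 and reversed in 5. Named genes did so in 4622, 407, 3 and 8 cases. Direction was compared only for lists and genes called in the main result. Reversed means a changed direction, whether or not the new direction passed the threshold. Other list tests are not in that tally: by genotype camera called 17 lists with the preset and 3 with an estimated correlation, and fry and the added list scores per animal called 22 each. Other results stayed within 1.5 times or on their side in 254 cases, moved in 71 and lost the call in 18. The cause was not tested, except that settings with fewer arrays or a stricter threshold have less power by construction. No paired analysis was possible because the labels give no shared replicate numbers. Background correction, median scaling and detection over all 80 arrays, and list tests with chip as a random block, were not run. Signal over background limits dim genes most, and detection is known for 32 arrays.

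Beside Pkd1, named genes kept or lost calls as follows, where a gene counts once for each comparison that names it. Of 171, 59 lost the call on chips E to J alone, 27 on chips A to D alone, 17 without a chip term, 15 at an adjusted p below 0.01, 14 without chip B, 9 without C, 9 without D, 8 without E, 2 to 6 without each other chip, and 6 without the mutant with the heaviest kidneys. On chips A to D 25 lost it with neqc and, among added settings, 31 without background correction, 34 with median scaling and 31 in the consolidated table. With only mutants no heavier in kidney than the highest control 79 lost it, 33 stayed on their side of the threshold and 7 reversed in sign.

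Without a detection filter Pkd1 lost its call (-0.08). Without a chip term Pkd1 (-0.07) and gluconeogenesis (-0.22) lost theirs, and counts were 544 in females, 2136 in males, 16 for the interaction, 1901 for sex in controls, 4337 for age in controls and 917 for the age difference. With chip as a random block age in controls gave 29. Array weights gave 67 interaction genes and 9 for age in controls, and glutathione genes gained a call (-0.10).

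On chips A to D alone Pkd1 was -0.07 with no call, and counts were 4 for the interaction, 1483 for sex in controls, 1237 for sex in mutants, 1 for age in controls and 0 for the age difference (limma, 2224 at an unadjusted p below 0.05). The male body weight difference was -3.6061 g (exact permutation p = 0.114). On chips E to J alone Hsd11b1 reversed (-0.01). Calls were lost for Pkd1 (-0.09), fatty acid oxidation (-0.02), peroxisomal oxidation (-0.01), gluconeogenesis (-0.07), proximal tubule (-0.04) and endothelial markers (0.04), and glutathione genes gained one (-0.11). Counts there were 1022 for genotype, 131 in females, 1103 in males, 11 for the interaction, 1042 for the kidney weight slope, 0 for age in controls (limma, 618 unadjusted) and 0 for the age difference (limma, 567 unadjusted).

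Without chip A there were 17 interaction genes and 9 for age in controls. Without chip B Pkd1 (-0.08) lost its call, glutathione genes (-0.07) gained one, the kidney weight slope gave 1890 and age in controls 1. Without chip C Pkd1 (-0.08) and gluconeogenesis (-0.21) lost calls, with 334 genes in females, 0 for age in controls (limma, 464 unadjusted) and 1287 for the age difference. Without chip D Pkd1 (-0.07) and gluconeogenesis (-0.20) lost calls, glutathione genes (-0.12) gained one, females gave 565 and age in controls 1. Pkd1 lost its call without chip E (-0.07), G (-0.07) and I (-0.07), and gluconeogenesis without J (-0.25). The interaction gave 14 without E, and age in controls 1 without F, 5 without I and 4 without J. Without the mutant with the heaviest kidneys Pkd1 was -0.08 with no call, glutathione genes were called (-0.09) and the interaction gave 41.

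With only mutants no heavier in kidney than the highest control of both sexes and all chips, counts were 275 for genotype, 116 in females, 238 in males and 7 lists. These mutants were picked by an outcome and form no group of the study. Reversed in sign, or for lists in camera direction, were Cdkn1c (0.00), Cd79b (-0.02), Ifit2 (-0.01), Bicc1 (-0.06), Slco1a1 (0.05), Abcc3 (-0.01), Hnf4a (0.00), fatty acid oxidation (0.05), peroxisomal oxidation (0.06), gluconeogenesis (0.04), proximal tubule (0.05) and matrix genes (0.00). These values lie between -0.06 and 0.06, and no opposite change is read from them. Calls were lost for Pkd1 (-0.09), citric acid cycle (-0.01), endothelial (0.03), lymphocyte (-0.01), injury (0.02) and interferon genes (0.06). The kidney weight slope gave 491 on ranks and 1839 without the 2 animals farthest from the median ratio.

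With neqc on chips A to D Pkd1 was -0.11 with no call, and counts were 3 for the interaction, 1448 and 1226 for sex in controls and mutants, 1 for age in controls and 147 for the age difference. At an unadjusted p below 0.05 there were 2539 genes in females, 1069 for the interaction, 641 for age in controls and 3475 for the age difference. At an adjusted p below 0.01 Pkd1 (-0.08) lost its call, with 433 in females, 12 for the interaction, 1989 for the kidney weight slope, 1 for age in controls and 1128 for the age difference.

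Of the added settings, detection on all 32 arrays lost gluconeogenesis (-0.24). Chips A to D without background correction gave Pkd1 at -0.26 with no call, 1 interaction gene, 1400 and 1163 for sex in controls and mutants, 1 for age in controls and 118 for the age difference. With neqc and median scaling Pkd1 was -0.08 with no call, male-biased (-0.27) and fat cell genes (-0.24) gained calls, and counts were 604 in females, 2 for the interaction, 1102 and 1142 for sex, 5 for age in controls and 371 for the age difference. The consolidated table gave Pkd1 at -0.01 with no call, 2 interaction genes, 1799 and 1417 for sex and 17 for the age difference.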

Other observations

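The test of female-biased genes and the choice of the other Serpina genes came only after related results were seen.

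Other members of the Serpina family were also measured. Serpina1a, an alpha-1-antitrypsin gene, differed by 0.89 in females and 0.09 in males (limma adjusted p of the difference 0.0086), and Serpina1c by 0.48 and -0.03 (adjusted p of the difference 0.0947). Serpina1f was higher in both sexes, by 0.41 in females and 0.28 in males (limma adjusted p of the difference 0.776). Serpina3n differed by 0.47 and 0.91 and Serpina5 by -0.01 and 0.01. Serpina10, which encodes an inhibitor of coagulation factor X, was higher by 1.45 in mutant females and 2.17 in mutant males, and Serpina3g by 1.06 and 1.35.

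Genes that were higher in control males fell with kidney weight in mutants of both sexes. The mean over 1288 such genes changed by -0.16 (SE 0.033) per doubling of the kidney to body weight ratio in 26 mutant males and by -0.11 (SE 0.027) in 21 mutant females. A shift of mutant male kidneys toward the female pattern is a candidate explanation, as a hypothesis. It needs genes that were higher in control females to rise in mutant males, and the mean over 1579 of them rose by 0.08 (SE 0.018). In mutant females their slope was 0.01 (SE 0.012), and whether the slopes differ between the sexes was not tested. The fall of male-biased genes in females as well is not accounted for by such a shift in males alone. Changes in cell makeup and injury stay open as another source of these slopes: per doubling, scores of proximal tubule markers changed by -0.44 (SE 0.065), of injury genes by 0.64 (SE 0.077) and of matrix genes by 0.50 (SE 0.085) in mutants. In controls, the male minus female scores of injury genes were -0.21 (adjusted p = 0.212) and of matrix genes -0.17 (adjusted p = 0.292).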
